A study of Arabidopsis thaliana with 8 samples.

How the data were processed

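RNA was sequenced from Arabidopsis thaliana seedlings grown for 5 days in the dark on medium with BRZ (brassinazole), an inhibitor of brassinosteroid synthesis. There were 4 genotypes with 2 libraries each. Col-0 is the wild type, bzr1-1D carries a dominant allele that stabilises the brassinosteroid-responsive transcription factor BZR1, pifq lacks the phytochrome-interacting factors PIF1, PIF3, PIF4 and PIF5, and pifq;bzr1-1D combines both. Total RNA was extracted with a column kit and made into libraries with Illumina's TruSeq RNA kit, per the labels' protocols. Each library's genotype and replicate number come from its title. The labels do not say whether the 2 libraries of a genotype came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

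The deposited values are whole-number counts of reads per gene, 1 file per library, with 33518 genes in each file. TopHat and HTSeq and the TAIR9 build are named in the submitters' processing notes. Their versions, the strand setting and the treatment of reads with several hits are not given in the sources used here. Genes with near-identical copies (LHCB1 and LHCB2 genes, RBCS genes, XTH17 to XTH19, SAUR19 to SAUR24, the SESA genes, AT5G50565 with AT5G50665) are therefore uncertain one by one, as are overlapping and antisense genes. Reads that HTSeq assigned to no gene made up 2.68% to 4.27%, and ambiguous reads 1.95% to 2.08%, of the gene counts and the HTSeq summary classes together. Both stayed out of library sizes and tests. The annotation used for names and gene order was that of TAIR10.1, which is another build than the one the counts were made on, so no coordinates are given. It held 32709 of the gene codes, and 809 had no match there.

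Library totals were 16.1 to 34.4 M gene counts (M, mega). A count of 0 allows up to 3 counts with 95% confidence, which is 0.0872 to 0.186 CPM (counts per M gene counts) depending on the library. Such floors cover counting error only, since the reads carry no molecular identifiers. No fold is given where every library of a genotype had 0 counts, or only 1 to 3, unless it is said to be a fitted value.

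Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with TMM factors (0.942 to 1.04), after filterByExpr had left 21221 genes. All 8 libraries entered 1 fit with a mean per genotype and 4 residual degrees of freedom, because 2 libraries per genotype give too little to estimate the spread pair by pair. The 5 contrasts were bzr1-1D against Col-0, pifq against Col-0, pifq;bzr1-1D against pifq, pifq;bzr1-1D against bzr1-1D, and the interaction, which is the bzr1-1D effect without the PIFs minus that with them. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute value divided by the square root of F. CPM values are given as means of 2 libraries.

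Lists of genes were fixed from general knowledge before the data were examined. They were 21 lists with 296 members, of which 292 were found in the annotation (PRE2, PRE4, DVR and F3PH were left out). Members removed by the count filter were not tested, which left 22 of 23 for auxin response, 16 of 19 for gibberellin, 10 of 11 for ethylene, 4 of 8 for flavonoid biosynthesis and 8 of 12 for defence and heat stress, and all members of the others. The lists were the mutated genes, brassinosteroid biosynthesis, brassinosteroid signalling, expansins and xyloglucan endotransglucosylases, helix-loop-helix growth regulators, auxin biosynthesis and transport, auxin response, gibberellin, ethylene and apical hook, shade and phytochrome targets, light-induced regulators, photosystems and light harvesting, carbon fixation, chlorophyll and haem biosynthesis, flavonoid biosynthesis, cellulose synthases, the circadian clock, stomatal lineage, root markers, seed storage, and defence and heat stress. The list named brassinosteroid biosynthesis for short is that of biosynthesis and inactivation, with BAS1 as its inactivating gene. Each list was tested in each contrast with camera of limma 3.58.1 on log2 CPM (inter-gene correlation 0.01, prior count 2), adjusted over all 105 tests. Camera with an estimated correlation and fry were alternatives. Fry asks whether the members of a list move, on balance, one way, and does not compare them with other genes.

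The genes named in the text follow a rule that was also fixed then. It takes the 5 mutated genes, the 6 highest and 6 lowest fold changes per contrast among called genes with a mean of 10 CPM or more in the higher genotype and non-overlapping replicates (the last not for the interaction), and up to 4 members of each list by smallest p. Some were left out for length. Genes named outside this rule are said to be so.

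The bzr1-1D and pifq contrasts share the Col-0 libraries. Unchanged genotypes were therefore simulated against them 20 times. The 2 libraries of each genotype were compared first and differed by more than counting noise, with a median chi-square per gene of 0.559 to 0.644 against 0.455 from counting alone (genes with 20 or more counts in the pair). Counting noise alone is the only spread ruled out by this, and it does not show that the samples were independent. The libraries were kept as 2 samples per genotype because the labels list them so. Their log2 CPM values correlated at r = 0.997 to 0.998 across genes. The common dispersion of 0.000779 is a coefficient of variation of 2.79%.

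The procedure was tested on simulated data of 20594 genes with known changes. In bzr1-1D against Col-0, where 67, 67 and 66 genes were changed by 1.5-fold, 2-fold and 4-fold, it recovered 82.1%, 92.5% and 97.0% of them. For the interaction these shares were 65.7%, 82.1% and 93.9%. Every recovered change had the right direction. Unchanged genes made up 6.05% of the calls in pifq;bzr1-1D against pifq, 9.5% in bzr1-1D against Col-0 and 10.6% in both pifq;bzr1-1D against bzr1-1D and the interaction, above the nominal share of the adjustment. Far fewer genes were changed there than were called in the real data, so these rates need not be those of the reported calls. None of the 105 list tests passed in the simulated counts. Genes were drawn there independently of each other, with changes not tied to the lists. This therefore does not check the list tests where genes vary together.

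Alternatives chosen before the data were examined were RLE size factors, no filter, a stricter filter (10 CPM in 2 libraries), DESeq2 1.42.0, the replicate number as a block, thinning to the smallest total, leaving out organelle genes or the 20 most abundant genes, fitting only the 2 genotypes compared, and leaving out each of the 8 libraries in turn. Average effects over both backgrounds were a further alternative for the overlap. A restriction to chromosomes 2, 3 and 4, the choice of genes by the p of their average effect, and a split of the Col-0 libraries between both comparisons (3 residual degrees of freedom) were added after seeing the data. Tables were handled with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.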

Results

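The transcriptomes of dark-grown seedlings of the wild type Col-0, the single lines bzr1-1D and pifq, and their combination pifq;bzr1-1D were compared on medium with a brassinosteroid synthesis inhibitor. The series addresses how the brassinosteroid-responsive factor BZR1 and the phytochrome-interacting factor PIF4 act together. On this medium the seedlings make little brassinosteroid of their own, while the bzr1-1D allele keeps BZR1 active. The Col-0 libraries held 34.4 and 20.5 M gene counts (M, mega), those of bzr1-1D 25.6 and 24.3 M, those of pifq 25.8 and 24.6 M, and those of pifq;bzr1-1D 29.5 and 16.1 M. The 20 most abundant genes took 7.70% to 8.46% of the counts in Col-0 and bzr1-1D and 10.8% to 12.7% in both genotypes without the PIFs. Chloroplast-encoded genes took 0.460% to 0.646% in the first pair of genotypes and 0.934% to 1.5% in the second pair.

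PIF1, PIF3 and PIF5 transcripts were lower in pifq than in Col-0, and PIF4 transcripts were higher. PIF1 (AT2G20180) had a mean of 45.8 CPM in Col-0, 43.5 in bzr1-1D, 22.0 in pifq and 20.7 in pifq;bzr1-1D. PIF3 (AT1G09530) had 202, 161, 112 and 123 CPM in the same order, and PIF5 (AT3G59060) had 34.4, 33.7, 11.4 and 20.9. PIF4 (AT2G43010) had 14.2, 13.6, 25.5 and 48.7 CPM, and its log2 fold change in pifq was 0.85 ± 0.07 (SE, n = 2 per genotype, edgeR quasi-likelihood adjusted p = 1.53e-12). BZR1 (AT1G75080) had 38.5, 41.8, 33.5 and 48.3 CPM. Its rise in bzr1-1D, a log2 fold change of 0.13 ± 0.05 with an edgeR adjusted p of 0.0348, was lost when any library but Col-0 replicate 2 and bzr1-1D replicate 1 was left out (adjusted p = 0.0960 to 0.333) and under 5 other alternatives, DESeq2 and thinning among them (adjusted p = 0.0594 to 0.488). In pifq;bzr1-1D against pifq, BZR1 rose by a log2 fold change of 0.52 ± 0.05. Counts per gene do not show which part of a transcript was read, and bzr1-1D changes the protein, so transcript levels of PIF4 and BZR1 do not check the genotypes. Genotype names are used as the labels give them.

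**Figure D1:**
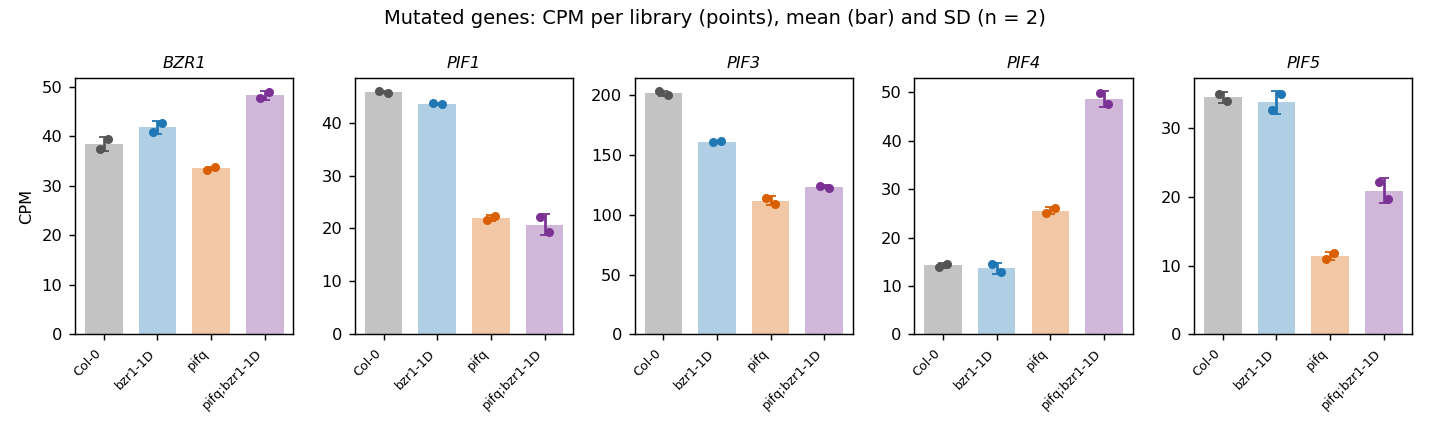
CPM of BZR1, PIF1, PIF3, PIF4 and PIF5 (vertical axes, starting at 0) in each library (points), with the mean (bars) and SD (error bars) of the 2 libraries of each genotype. PIF1, PIF3 and PIF5 were lower in pifq than in Col-0, whereas PIF4 was 14.2 CPM in Col-0, 25.5 in pifq and 48.7 in pifq;bzr1-1D.

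The comparison of bzr1-1D with Col-0 asks what active BZR1 does where the PIFs are present. Most of the genes for brassinosteroid synthesis tested fell in bzr1-1D. BR6OX2, an oxidase that makes brassinolide, went from 346 to 30.3 CPM (log2 fold change −3.51 ± 0.04 SE, n = 2 per genotype), and DWF4, a C-22 hydroxylase of the pathway, from 108 to 29.5 CPM (−1.86 ± 0.05). Most auxin response genes tested rose, among them IAA19 from 5.4 to 34.9 CPM (2.67 ± 0.09), SAUR9 from 3.13 to 26.2 CPM (3.09 ± 0.10) and GH3.2, which conjugates auxin, from 11.8 to 42.4 CPM (1.83 ± 0.07). The cell wall enzyme genes XTH18 (log2 fold change 3.91 ± 0.06), XTH19 (2.26 ± 0.05) and XTH30 (1.59 ± 0.04) rose, while the seed storage genes CRU3 and CRA1 fell from 84.6 to 0.548 and from 80.2 to 0.707 CPM. Of 21221 genes tested, 12064 were called, 6528 higher and 5536 lower, and 2415 of them differed by 2-fold or more.

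Of the 11 genes of brassinosteroid biosynthesis and inactivation measured, 7 fell, 2 rose and 2 were not called, with CPD (−0.96 ± 0.03) and CYP90D1 (−2.60 ± 0.11) among those that fell (camera adjusted p = 0.00534, but adjusted p = 0.161 with an estimated correlation). In the auxin response list, 16 of 22 rose and 3 fell (camera adjusted p = 0.000803, but adjusted p = 0.147 with an estimated correlation). The photosystem and light-harvesting list had 22 of 33 members higher and 4 lower, with LHCB2.3 at 0.99 ± 0.04, LHCB1.2 at 0.68 ± 0.03 and LHCB3 at 0.56 ± 0.04 (camera adjusted p = 0.0127, but adjusted p = 0.612 with an estimated correlation). Without Col-0 replicate 1 this list no longer passed (adjusted p = 0.0669). Chlorophyll and haem genes went the other way, with 14 of 20 lower and 3 higher. HEMA1, which starts the pathway, had −0.53 ± 0.03 and CHLD −0.36 ± 0.04, against 0.79 ± 0.04 for HY1, a haem oxygenase (camera adjusted p = 0.0212, but adjusted p = 0.175 with an estimated correlation).

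Root marker genes fell in bzr1-1D, 9 of 11 lower and 1 higher. PRP3, a root hair wall protein gene, had 5.19 CPM in Col-0 and 0.198 in bzr1-1D, whereas LRX2 rose from 5.20 to 33.8 CPM (camera adjusted p = 0.00534, but adjusted p = 0.161 with an estimated correlation). Seed storage and late embryogenesis genes fell, 9 of 12 with none higher, SESA5 by a log2 fold change of −3.65 ± 0.20 (camera adjusted p = 0.000266, but adjusted p = 0.147 with an estimated correlation). The median log2 fold change of the seed list was −3.25, or −2.84 with SESA2, at 0 counts in bzr1-1D, set against the floor of 3 counts per library.

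Other lists did not pass as lists in bzr1-1D, though members were called. Expansins and xyloglucan endotransglucosylases had 14 of 23 higher and 8 lower (camera adjusted p = 0.164), with XTH4 at 1.48 ± 0.03. Helix-loop-helix growth regulators had 5 of 10 higher and 4 lower (0.965), PRE6 at 1.18 ± 0.06 and HFR1 at −0.61 ± 0.05. Brassinosteroid signalling had 5 of 13 higher and 4 lower (0.931), or 7 higher and 4 lower adjusted over the list alone, and the closest relatives of BZR1 named there, BES1 (−0.77 ± 0.04) and BEH2 (−0.63 ± 0.04), fell. Gibberellin genes had 8 of 16 higher and 4 lower (0.357), with GASA6 at 1.27 ± 0.06 and the synthesis gene GA3OX1 at 0.95 ± 0.05. Auxin biosynthesis and transport (5 of 14 higher, 1 lower), ethylene and apical hook (4 of 10 higher, 3 lower) and shade and phytochrome targets (2 of 14 higher, 5 lower) had camera adjusted p of 0.264, 0.91 and 0.124. For the other lists fixed, the camera adjusted p was 0.532 for the mutated genes, 0.678 for light-induced regulators, 0.164 for carbon fixation, 0.446 for flavonoid biosynthesis, 0.891 for cellulose synthases, 0.66 for the clock, 0.417 for the stomatal lineage and 0.246 for defence and heat stress. In all lists but brassinosteroid signalling the counts adjusted over the list alone were those given over all genes. Median and mean differed in sign for light-induced regulators (0.03 and −0.07) and the clock (−0.06 and 0.05), and both lists had a downward test.

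Among genes with 10 CPM or more in the higher genotype, the 6 highest and 6 lowest fold changes of this comparison lay on chromosomes 1 and 5. Below that level others did not, such as AT3G30420 on chromosome 3 with 0 counts in Col-0 and 3.07 CPM in bzr1-1D. AT5G35965 had 0 counts in Col-0 and a mean of 13.4 CPM in bzr1-1D, and AT1G24370 had 0.0888 and 38.2 CPM. AT5G28145 had 327 CPM in Col-0 and 1.07 in bzr1-1D, AT1G20390 had 492 and 2.92 CPM, and AT5G50665 had 24.5 and 0.0584 CPM. Counted after the values were seen, 41 genes were over 16-fold lower in bzr1-1D than in each of the other 3 genotypes (0.1 CPM added), and 38 of them, CRA1 included, lay on chromosomes 1 and 5, against 49.5% of all nuclear genes tested. CRU3, on chromosome 4, was another of the 41. With genes of chromosomes 2, 3 and 4 alone, a choice also made after the values were seen, the camera adjusted p in bzr1-1D was 0.368 for auxin response (12 members), 0.0507 for brassinosteroid biosynthesis (8), 0.221 for chlorophyll and haem and 0.125 for root markers, while photosystems (0.0257) and seed storage (0.0414) still passed.

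**Figure D2:**
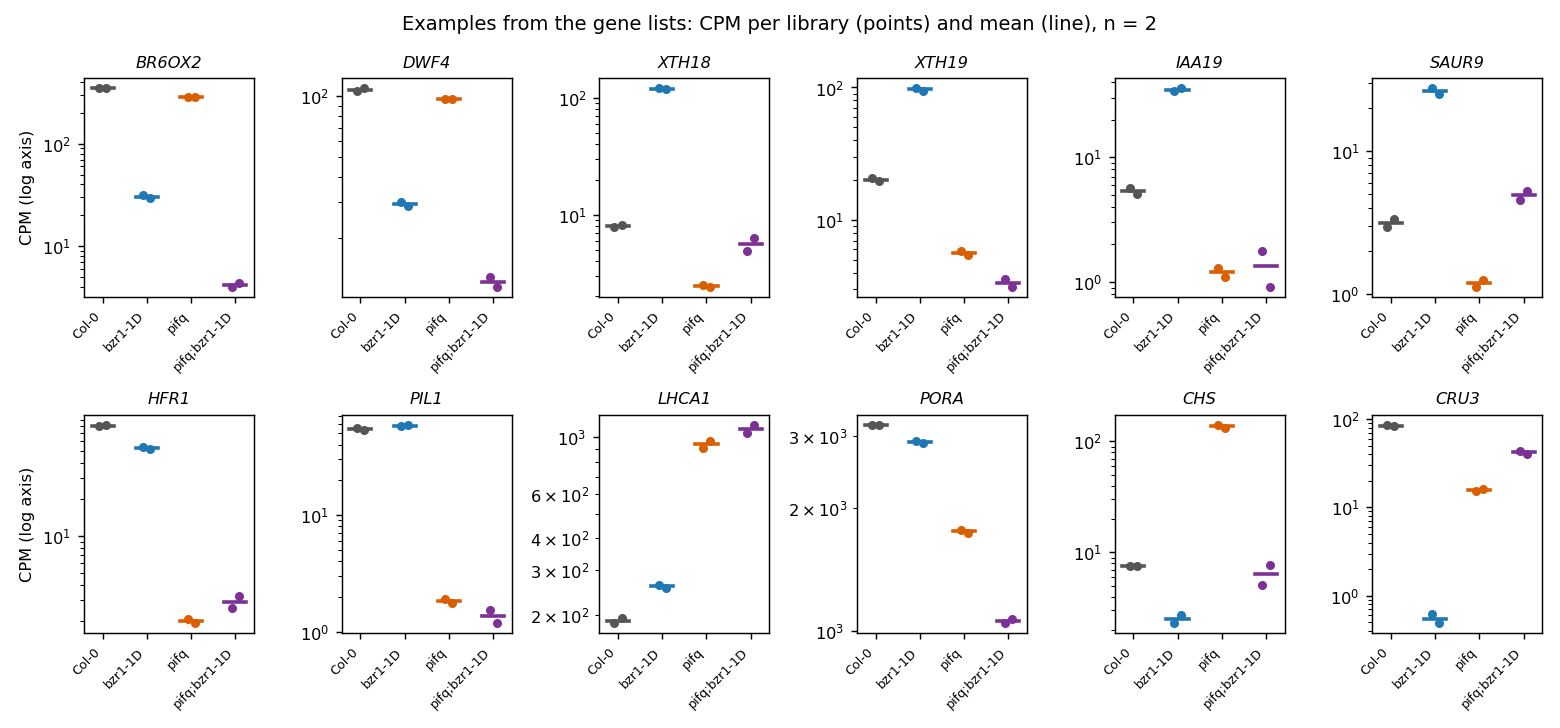
CPM on log axes for 12 genes in each library (points), with the mean of the 2 libraries of each genotype (lines). BR6OX2 and DWF4 were lower in both genotypes with bzr1-1D, XTH18, XTH19, IAA19 and SAUR9 were highest in bzr1-1D, HFR1 and PIL1 were lower and LHCA1 higher in both genotypes without the PIFs, CHS was highest in pifq at 137 CPM, and CRU3 was lowest in bzr1-1D.

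The comparison of pifq with Col-0 asks what the 4 PIFs do in the dark on the same medium. Genes of photosynthesis rose in pifq, and most of the shade and auxin response genes tested fell. All 33 photosystem and light-harvesting genes measured were higher, LHCA1 going from 189 to 942 CPM (log2 fold change 2.32 ± 0.04 SE, n = 2 per genotype). PIL1, a shade-induced bHLH gene, fell from 54.1 to 1.83 CPM (−4.88 ± 0.09), HFR1, which restrains the PIFs, from 80.1 to 2.01 CPM (−5.31 ± 0.08), and the homeobox gene ATHB2 from 75.8 to 8.26 CPM (−3.20 ± 0.06). CHS, the entry enzyme of flavonoid synthesis, rose from 7.56 to 137 CPM (4.18 ± 0.07), and the iron transporter gene IRT1 from 0.173 to 30.0 CPM. In total 13267 of 21221 genes were called, 6789 higher and 6478 lower, and 2686 differed by 2-fold or more.

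LHCB3 (1.95 ± 0.04), PSAH2 (1.79 ± 0.03) and LHCB2.2 (1.85 ± 0.04) were among the photosystem genes that rose (camera adjusted p = 3.88e-16, but adjusted p = 0.258 with an estimated correlation). All 12 carbon fixation genes were higher, with RCA, which activates Rubisco, at 0.89 ± 0.04 and GAPB at 0.84 ± 0.04 (camera adjusted p = 1.96e-05, but adjusted p = 0.156 with an estimated correlation). Of 20 chlorophyll and haem genes, 17 rose and 3 fell. GUN4 (1.51 ± 0.04), PORC (1.63 ± 0.05) and CHLI1 (0.96 ± 0.03) rose, while PORA, the protochlorophyllide reductase of etiolated tissue, fell from 3195 to 1756 CPM (camera adjusted p = 6.28e-05, but adjusted p = 0.147 with an estimated correlation). The flavonoid list had 3 of 4 members higher, FLS1 by 4.17 ± 0.14 and CHI by 2.14 ± 0.12 (camera adjusted p = 0.0327, but adjusted p = 0.227 with an estimated correlation). Stomatal lineage genes had 7 of 10 higher and 1 lower, with SPCH at 2.05 ± 0.18 and TMM at 1.36 ± 0.11 (camera adjusted p = 0.0154, but adjusted p = 0.287 with an estimated correlation). The higher share of chloroplast-encoded counts given above went with these groups.

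Shade and phytochrome targets fell, 11 of 14 with 2 higher, among them ST2A (−3.26 ± 0.05) and PIL2 (−3.26 ± 0.06) (camera adjusted p = 0.000266, but adjusted p = 0.147 with an estimated correlation). Auxin response had 18 of 22 lower and 1 higher, with GH3.5 at −1.49 ± 0.04, IAA17 at −1.69 ± 0.05 and IAA29 at −1.55 ± 0.08 (camera adjusted p = 8.81e-07, but adjusted p = 0.133 with an estimated correlation). Ethylene and apical hook genes had 8 of 10 lower and none higher, including HLS1 (−1.54 ± 0.09), which is needed for the hook (camera adjusted p = 0.00261, but adjusted p = 0.161 with an estimated correlation). Helix-loop-helix regulators had 7 of 10 lower and 1 higher, HFR1 and PRE6 (−1.73 ± 0.08) among them (camera adjusted p = 0.00923, but adjusted p = 0.23 with an estimated correlation). Of the members lower in pifq, IBH1 (−3.15 ± 0.11) lies 4 tested genes after PIF4 and PAR1 (−0.93 ± 0.05) 13 before it in the order of TAIR10.1. Brassinosteroid biosynthesis and inactivation had 9 of 11 lower and 1 higher, with ROT3 at −0.86 ± 0.04 and CPD at −0.50 ± 0.03 (camera adjusted p = 0.0176, but adjusted p = 0.175 with an estimated correlation).

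Gibberellin genes had 8 of 16 lower and 1 higher, with GASA4 at −2.40 ± 0.08 and the DELLA genes GAI at −1.06 ± 0.05 and RGA at −0.71 ± 0.04 (camera adjusted p = 0.0311, but adjusted p = 0.287 with an estimated correlation). Expansins and xyloglucan endotransglucosylases had 14 of 23 lower and 8 higher, with EXPA11 at −2.33 ± 0.04 and XTH15 at −1.74 ± 0.03 (camera adjusted p = 0.033, but adjusted p = 0.404 with an estimated correlation). Cellulose synthases had 7 of 8 lower and 1 higher, CESA1 by −0.74 ± 0.04 and CESA5 by 0.84 ± 0.05 (camera adjusted p = 0.0476, but adjusted p = 0.458 with an estimated correlation). This last call was lost with RLE size factors (adjusted p = 0.0527) and without Col-0 replicate 1, bzr1-1D replicate 1, bzr1-1D replicate 2 or pifq replicate 2 (adjusted p = 0.0502 to 0.0769). Lists that did not pass were the mutated genes (0.099), brassinosteroid signalling (5 of 13 higher, 7 lower, 0.279), auxin biosynthesis and transport (0.408), light-induced regulators (6 of 12 higher, 4 lower, 0.264), the clock (0.219), root markers (0.334), seed storage (0.124) and defence (0.336), each with its camera adjusted p. Root markers had a median of −0.75 and a mean of 0.00. Auxin biosynthesis and transport had 7 of 14 higher and 4 lower, or 8 and 4 adjusted over the list alone, and the clock had 1 of 11 higher and 5 lower, or 3 and 5 adjusted over the list alone. Counts adjusted over the list alone did not differ for the other lists. With genes of chromosomes 2, 3 and 4 alone, and so fewer members, 8 list calls in pifq were lost (camera adjusted p in brackets), those of brassinosteroid biosynthesis (0.0836), expansins and xyloglucan endotransglucosylases (0.368), helix-loop-helix regulators (0.0859), gibberellin (0.482), ethylene (0.0507), flavonoid biosynthesis (0.269, 1 member), cellulose synthases (0.108) and stomatal lineage (0.654).

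Several of the genes that fell most in pifq neighbour each other. CSY3, a citrate synthase gene, fell from 94.2 to 0.472 CPM (−7.61 ± 0.12), and AT2G42750 from 47.0 to 0.299 CPM. AT2G42780 had 22.6 CPM in Col-0 and 0.118 in pifq. By the gene order of TAIR10.1 these 3 genes and AT2G42770 lie 20 to 24 tested genes before PIF4 on chromosome 2. DMT2, a DNA methyltransferase gene, fell from 172 to 2.44 CPM and was also low in bzr1-1D at 8.39 CPM.

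The comparison of pifq;bzr1-1D with pifq asks what active BZR1 does where the 4 PIFs are missing. Most brassinosteroid synthesis genes and all flavonoid genes tested fell. BR6OX2 went from 285 to 4.21 CPM (log2 fold change −6.10 ± 0.06 SE, n = 2 per genotype), DWF4 from 97.0 to 12.2 CPM (−2.97 ± 0.06), CHS from 137 to 6.38 CPM (−4.50 ± 0.08) and FLS1 from 17.8 to 1.35 CPM (−3.77 ± 0.15). Most auxin response genes tested rose, GH3.2 from 10.8 to 31.8 CPM (1.53 ± 0.08) and IAA3 from 24.7 to 45.7 CPM (0.90 ± 0.06). The largest rises among the genes named by the rule were those of PXMT1 (6.07 ± 0.15), AT1G26240 (5.45 ± 0.24), the peroxidase gene PER4 (5.20 ± 0.18) and SESA5 (5.18 ± 0.21). Here 11860 genes were called, 5958 higher and 5902 lower, and 1617 differed by 2-fold or more.

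Brassinosteroid biosynthesis and inactivation had 8 of 11 lower and 2 higher, with CYP90D1 at −3.03 ± 0.14 and BR6OX1 at −2.90 ± 0.17 (camera adjusted p = 0.00477, but adjusted p = 0.161 with an estimated correlation). All 4 flavonoid genes tested were lower (camera adjusted p = 0.00772, but adjusted p = 0.17 with an estimated correlation). Auxin response had 14 of 22 higher and 3 lower, or 14 and 4 adjusted over the list alone, and GH3.3 fell by −0.88 ± 0.06 (camera adjusted p = 0.00261, but adjusted p = 0.156 with an estimated correlation). Clock genes rose, 8 of 11 with 1 lower, including PRR7 (0.76 ± 0.04), TOC1 (0.57 ± 0.04) and LUX (0.54 ± 0.04) (camera adjusted p = 0.00468, but adjusted p = 0.161 with an estimated correlation). Chlorophyll and haem genes had 14 of 20 lower and 3 higher, PORA by −0.73 ± 0.03 and PORC by −0.71 ± 0.05 (camera adjusted p = 0.00989, but adjusted p = 0.161 with an estimated correlation). Carbon fixation had 9 of 12 lower and 1 higher, RCA by −0.59 ± 0.04 (camera adjusted p = 0.0266, but adjusted p = 0.287 with an estimated correlation). Light-induced regulators had 7 of 12 lower and 2 higher, with SIG2 at −0.59 ± 0.04 (camera adjusted p = 0.0307, but adjusted p = 0.287 with an estimated correlation).

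Seed storage genes had 9 of 12 higher and 1 lower in pifq;bzr1-1D against pifq. CRU3 rose from 15.7 to 42.3 CPM and CRA1 fell from 23.8 to 16.3 CPM (camera adjusted p = 0.0067, but adjusted p = 0.161 with an estimated correlation). Root markers had 7 of 11 lower and 1 higher, or 8 and 1 adjusted over the list alone, with PRP3 at 2.47 and 0.0981 CPM (camera adjusted p = 0.0179, but adjusted p = 0.175 with an estimated correlation). The mutated genes had 4 of 5 higher, PIF4 by 0.94 ± 0.06 and PIF5 by 0.89 ± 0.08 (camera adjusted p = 0.0476, but adjusted p = 0.251 with an estimated correlation). That call was lost without either Col-0 library, either pifq library or pifq;bzr1-1D replicate 1 (adjusted p = 0.0501 to 0.0872). The camera adjusted p was 0.301 for expansins and xyloglucan endotransglucosylases (12 of 23 higher, 9 lower), with EXPA8 at 1.66 ± 0.06 and XTH30 at 1.08 ± 0.05. It was 0.402 for gibberellin genes (8 of 16 higher, 4 lower), where GASA6 rose by 1.61 ± 0.05 and GA3OX1 fell by −1.34 ± 0.07, and 0.39 for photosystems (8 of 33 higher, 14 lower). It was 0.586 for brassinosteroid signalling, 0.197 for helix-loop-helix regulators, 0.81 for auxin biosynthesis and transport, 0.0939 for ethylene, 0.246 for shade targets, 0.143 for cellulose synthases, 0.357 for the stomatal lineage and 0.586 for defence. Adjusted over the list alone, auxin biosynthesis and transport had 5 of 14 higher and 7 lower, in place of 4 and 6. Ethylene had 7 of 10 higher in place of 6, and cellulose synthases 6 of 8 in place of 5. Restricted to chromosomes 2, 3 and 4, this comparison lost the calls of the mutated genes (camera adjusted p = 0.269), auxin response (0.331), carbon fixation (0.0578), chlorophyll and haem (0.112), flavonoid biosynthesis (0.313, 1 member), the clock (0.124) and root markers (0.728).

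The comparison of pifq;bzr1-1D with bzr1-1D asks what the 4 PIFs do where BZR1 is active. Most auxin response and shade genes tested fell and most light-harvesting genes rose. The cell wall enzyme gene XTH18 fell from 120 to 5.57 CPM (log2 fold change −4.48 ± 0.07 SE, n = 2 per genotype), XTH19 from 96.5 to 3.37 CPM (−4.81 ± 0.08), IAA19 from 34.9 to 1.34 CPM (−4.57 ± 0.13) and PIL1 from 58.2 to 1.36 CPM (−5.36 ± 0.10). LHCA1 rose from 258 to 1081 CPM (2.06 ± 0.04) and HEMA1 from 203 to 571 CPM (1.49 ± 0.03), while BR6OX2 fell from 30.3 to 4.21 CPM (−2.86 ± 0.09). In this comparison 13873 genes were called, 7167 higher and 6706 lower, and 3556 differed by 2-fold or more.

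Auxin response had 20 of 22 lower and 1 higher, with IAA17 at −2.04 ± 0.05 and SAUR9 at −2.45 ± 0.10 (camera adjusted p = 8.81e-07, but adjusted p = 0.133 with an estimated correlation). Shade and phytochrome targets had 9 of 14 lower and 1 higher, or 10 and 1 adjusted over the list alone, ST2A by −3.50 ± 0.05 and ATHB2 by −2.95 ± 0.06 (camera adjusted p = 0.000266, but adjusted p = 0.147 with an estimated correlation). Expansins and xyloglucan endotransglucosylases had 15 of 23 lower and 8 higher, XTH30 by −2.32 ± 0.04 (camera adjusted p = 0.0307, but adjusted p = 0.404 with an estimated correlation). Brassinosteroid biosynthesis and inactivation had 7 of 11 lower and 1 higher, ROT3 by −1.24 ± 0.05 (camera adjusted p = 0.0124, but adjusted p = 0.174 with an estimated correlation). Ethylene and apical hook had 8 of 10 lower and 1 higher, HLS1 by −1.53 ± 0.09 (camera adjusted p = 0.0154, but adjusted p = 0.215 with an estimated correlation). Gibberellin genes had 10 of 16 lower and 3 higher, GA3OX1 by −2.41 ± 0.07 and GASA1 by −1.55 ± 0.04 (camera adjusted p = 0.0377, but adjusted p = 0.287 with an estimated correlation). Without bzr1-1D replicate 1 the gibberellin call was lost (adjusted p = 0.0539). On chromosomes 2, 3 and 4 alone, with fewer members, expansins and xyloglucan endotransglucosylases (camera adjusted p = 0.331), gibberellin (0.34) and ethylene (0.124) did not pass, and carbon fixation did (0.0374).

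Photosystems and light harvesting had 31 of 33 higher and 1 lower in pifq;bzr1-1D against bzr1-1D, with LHCB1.3 at 1.85 ± 0.03 and LHCA4 at 1.41 ± 0.04 (camera adjusted p = 8.94e-12, but adjusted p = 0.294 with an estimated correlation). Chlorophyll and haem genes had 15 of 20 higher and 4 lower, HEMA1 among the former and PORA, at −1.46 ± 0.03, among the latter (camera adjusted p = 0.00261, but adjusted p = 0.156 with an estimated correlation). Seed storage genes had 11 of 12 higher and none lower, with CRU3 at 6.27 ± 0.13 and CRA1 at 4.52 ± 0.14 (camera adjusted p = 4.38e-05, but adjusted p = 0.147 with an estimated correlation). The camera adjusted p was 0.086 for carbon fixation, 0.586 for the mutated genes, 0.185 for brassinosteroid signalling, 0.132 for helix-loop-helix regulators, 0.892 for auxin biosynthesis and transport, 0.521 for light-induced regulators, 0.357 for flavonoid biosynthesis, 0.324 for cellulose synthases, 0.45 for the clock, 0.476 for the stomatal lineage, 0.865 for root markers and 0.696 for defence. Carbon fixation passed without pifq;bzr1-1D replicate 1 (adjusted p = 0.0473). Median and mean differed in sign for auxin biosynthesis and transport (0.09 and −0.04), light-induced regulators (0.18 and −0.30), flavonoid biosynthesis (0.89 and −0.21), root markers (−0.20 and 0.22) and defence (−0.01 and 0.19). For defence this came from 1 member at 0 counts in bzr1-1D, without which the mean was −0.34. Among the lowest genes were again AT2G42750 and CSY3 (−7.94 ± 0.13), and among the highest AT1G20390 (7.48 ± 0.10) and AT1G35115 (7.40 ± 0.11), which are 2 of the 41 genes nearly absent in bzr1-1D alone.

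**Figure D3:**
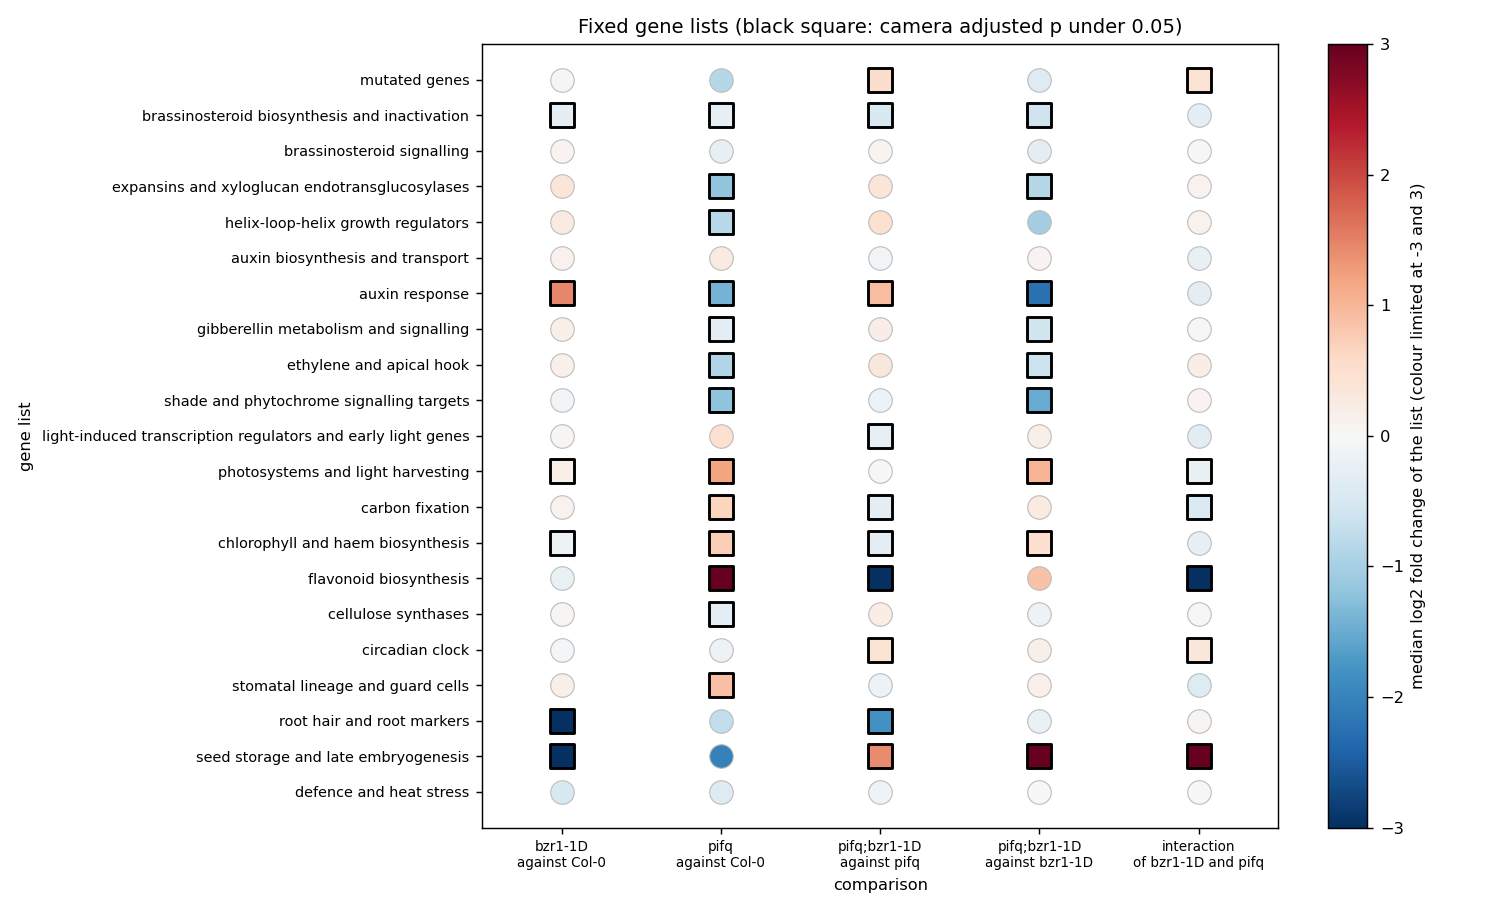
Median log2 fold change (colour, limited at −3 and 3) of each of the 21 fixed gene lists (vertical axis) in the 4 pairwise comparisons and the interaction (horizontal axis). Black squares mark the 44 of 105 tests with a camera adjusted p under 0.05, of which 0 passed with an estimated correlation. Photosystems were higher and auxin response lower in both comparisons of genotypes without and with the PIFs.

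The interaction asks whether the effect of bzr1-1D differs with and without the PIFs, and equally whether the effect of losing the PIFs differs with and without bzr1-1D. BR6OX2 fell more strongly in bzr1-1D when the PIFs were missing (interaction log2 −2.59 ± 0.09 SE, n = 2 per genotype), as did DWF4 (−1.11 ± 0.08). XTH19 rose in bzr1-1D with the PIFs and fell from 5.64 to 3.37 CPM without them (interaction −2.97 ± 0.15), and IAA19, which rose to 34.9 CPM in bzr1-1D, had 1.19 CPM in pifq and 1.34 in pifq;bzr1-1D (−2.39 ± 0.30). GA3OX1 rose with the PIFs and fell without them (−2.29 ± 0.09), and BES1 fell with them and rose from 88.7 to 116 CPM without them (1.16 ± 0.06). GA3OX1 and BES1 lie on chromosome 1, which holds 20 of the 41 genes nearly absent in bzr1-1D alone. For both genes, a sequence difference of the bzr1-1D line was not told apart from an interaction with the PIFs. An interaction was called by edgeR for 10363 of 21221 genes, 4646 with a positive and 5717 with a negative value, and 2271 of 2-fold or more.

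Seed storage genes had 9 of 12 positive interactions and none negative, with CRU3 at 8.70 ± 0.13 and SESA5 at 8.83 ± 0.29 (camera adjusted p = 1.1e-07, but adjusted p = 0.133 with an estimated correlation). All 4 flavonoid genes tested were negative, CHS by −2.91 ± 0.21 and FLS1 by −3.37 ± 0.37 (camera adjusted p = 0.0133, but adjusted p = 0.175 with an estimated correlation). Carbon fixation had 9 of 12 negative and 1 positive, RBCS1B by −0.92 ± 0.05 (camera adjusted p = 0.00986, but adjusted p = 0.227 with an estimated correlation). Photosystems had 22 of 33 negative and 5 positive, or 24 and 5 adjusted over the list alone, with LHCB2.3 at −1.72 ± 0.06 and LHCB4.2 at 0.68 ± 0.06 (camera adjusted p = 0.0112, but adjusted p = 0.612 with an estimated correlation). Clock genes had 7 of 11 positive and 2 negative, PRR7 by 0.79 ± 0.06 and TOC1 by 0.68 ± 0.05 (camera adjusted p = 0.0124, but adjusted p = 0.174 with an estimated correlation). The mutated genes had 4 of 5 positive, PIF4 by 0.99 ± 0.10 (camera adjusted p = 0.0156, but adjusted p = 0.175 with an estimated correlation). Among genes of chromosomes 2, 3 and 4 alone, the interaction of the mutated genes (camera adjusted p = 0.125), carbon fixation (0.0578) and flavonoid biosynthesis (0.342, 1 member) did not pass, and that of light-induced regulators did (0.0276).

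For the interaction of the other lists the camera adjusted p was 0.152 for brassinosteroid biosynthesis, 0.515 for brassinosteroid signalling, 0.678 for expansins and xyloglucan endotransglucosylases, 0.401 for helix-loop-helix regulators, 0.41 for auxin biosynthesis and transport, 0.127 for auxin response, 0.891 for gibberellin, 0.152 for ethylene, 0.701 for shade targets, 0.161 for light-induced regulators, 0.197 for chlorophyll and haem, 0.771 for cellulose synthases, 0.155 for the stomatal lineage, 0.263 for root markers and 0.865 for defence. Ethylene passed without bzr1-1D replicate 2 (adjusted p = 0.0442). Within these lists XTH16 (2.09 ± 0.07), XTH9 (0.90 ± 0.06), ERS2 (1.05 ± 0.08) and IAA1 (1.45 ± 0.13) had positive interactions, and YUC8 (−0.92 ± 0.13) and CKX5 (−1.11 ± 0.14) negative ones. Auxin response had 4 of 22 positive and 9 negative, or 4 and 10 adjusted over the list alone. Adjusted over the list alone, positive and negative counts were 5 and 3 in place of 4 and 3 for helix-loop-helix regulators and 5 and 4 in place of 4 and 4 for shade targets. The test was upward, against a negative mean, for brassinosteroid signalling (−0.11), expansins and xyloglucan endotransglucosylases (−0.21), gibberellin (−0.24), ethylene (−0.19), shade targets (−0.07) and cellulose synthases (−0.04). For ethylene this came from 1 member at 0 counts in both genotypes without the PIFs, without which the mean was 0.27. In 14 of the 105 tests over all comparisons the median, mean and test did not share a sign, or in 12 with members at 0 counts set to the floor or left out, and 0 of these passed.

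The most extreme interactions included genes that stood apart in 1 genotype. AT1G20390 (8.0 ± 0.12) and AT1G20400, at 0.0775 CPM in bzr1-1D and 18.2 in Col-0, were among the 41 genes nearly absent in bzr1-1D alone, as were CRU3 and CRA1. AT5G28145 had 327 CPM in Col-0 and 1.07 to 2.85 CPM in the other genotypes. AGP22 had 56.7 CPM in bzr1-1D and 3.93, 2.26 and 0.839 CPM in Col-0, pifq and pifq;bzr1-1D (−5.31 ± 0.26).

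**Figure D4:**
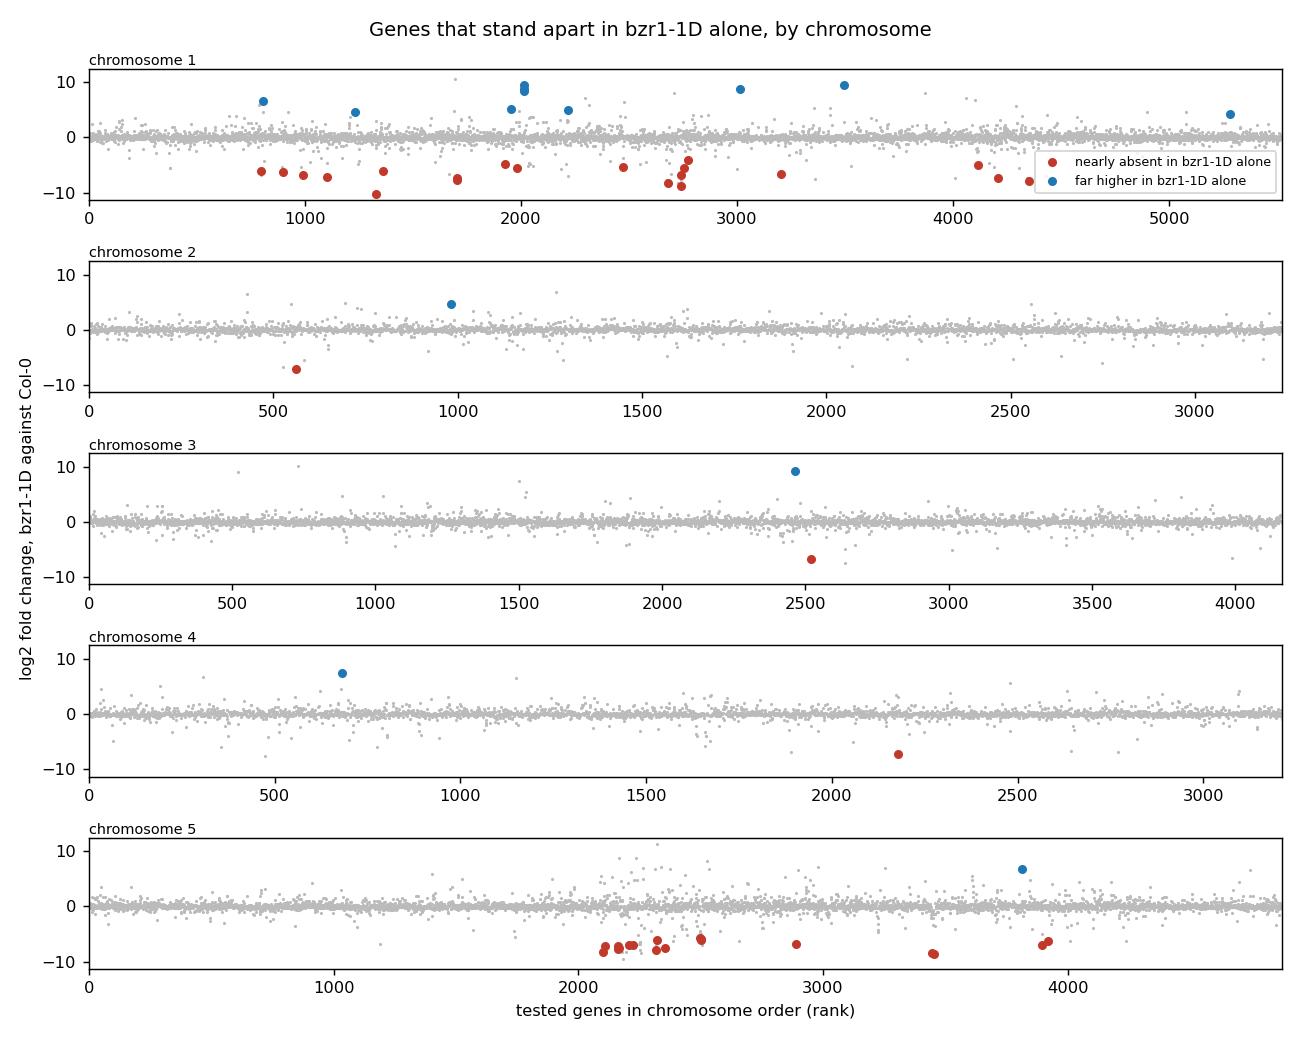
Log2 fold change of bzr1-1D against Col-0 (vertical axes) for the tested genes of chromosomes 1 to 5 in their TAIR10.1 order (horizontal axes, rank). Red points are the 41 genes nearly absent in bzr1-1D alone, 20 on chromosome 1 and 18 on chromosome 5, and blue points are the 14 genes far higher in bzr1-1D alone, 10 of them on chromosome 1.

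Across genes, the bzr1-1D effects with and without the PIFs went partly together. Of the 6528 genes higher in bzr1-1D than in Col-0, 2994 (45.9%) were also higher in pifq;bzr1-1D than in pifq, among them GH3.2 and GASA6, 912 (14.0%) were lower there, among them XTH19 and GA3OX1, and 2622 were not called. Of the 5536 lower genes, 2460 (44.4%) were lower there too, among them BR6OX2 and DWF4, 1249 (22.6%) were higher, among them BES1 and CRU3, and 1827 were not called. For GA3OX1 and BES1, on chromosome 1, a sequence difference of the bzr1-1D line was not told apart. For independent lists of these sizes, 1833 of the higher genes would be called the same way and 1816 the opposite way. For the lower genes these numbers would be 1540 and 1554. An interaction was called for 3810 of the 6528 (3284 towards a smaller effect without the PIFs) and for 3519 of the 5536 (2900 towards a smaller effect). The median log2 fold changes of the higher genes were 0.49 with and 0.18 without the PIFs, and those of the lower genes −0.39 and −0.14.

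Genes taken by their call in a contrast have inflated fold changes there. Read the other way, 50.3% of the genes higher and 41.7% of those lower in pifq;bzr1-1D against pifq were called the same way in bzr1-1D against Col-0. Of the interactions called for these genes, 2918 of 3657 and 3220 of 3673 went towards a larger effect without the PIFs. Their median log2 fold changes were 0.40 without and 0.16 with the PIFs for the higher genes, and −0.48 and −0.13 for the lower. The direction thus depended on which contrast chose the genes, so neither tally shows whether the effect is smaller or larger without the PIFs. For the 500 genes with the smallest p for a rise in the average of both bzr1-1D effects, a choice made after seeing the data, the medians were 0.99 with and 0.89 without the PIFs, and for the 500 with the smallest p for a fall −0.71 and −0.67. These genes were taken for a strong average, so they do not stand for all genes called. Over all tested genes the effects correlated at r = 0.365 (Spearman rho 0.316, across genes, which are not independent replicates), and the contrasts share no library. The pifq effects went together more often, 62.8% of the genes higher and 59.8% of those lower in pifq being called the same way in pifq;bzr1-1D against bzr1-1D. For independent lists of these sizes, 2293 of the 6789 higher and 2047 of the 6478 lower genes would be called so. More genes were called in the pifq contrasts, so more would agree there for independent lists too.

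**Figure D5:**
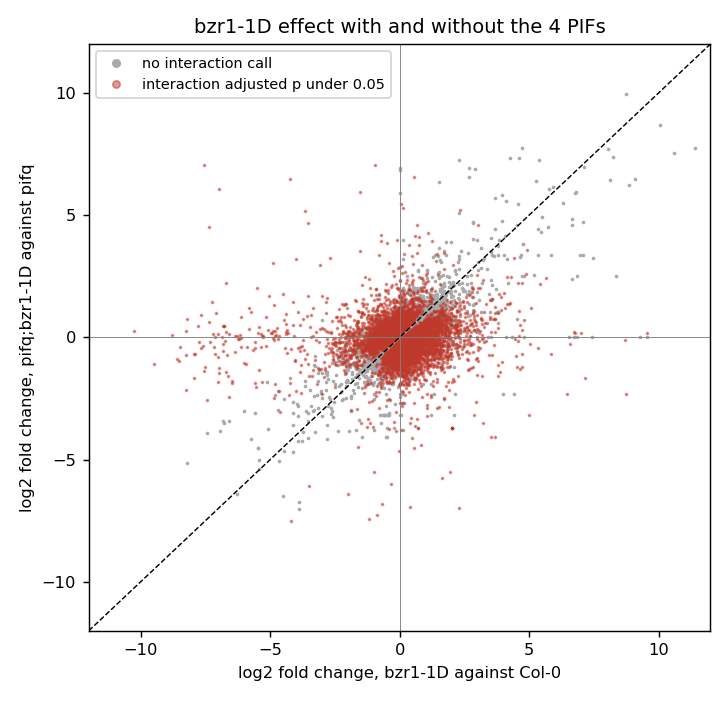
Log2 fold change of pifq;bzr1-1D against pifq (vertical axis) over that of bzr1-1D against Col-0 (horizontal axis) for each tested gene, with red points for the 10363 genes with an interaction call. The dashed line marks equal effects, and a band of red points along the horizontal axis holds genes changed in bzr1-1D against Col-0 with values near 0 without the PIFs. The band includes genes nearly absent or far higher in bzr1-1D alone, such as AT1G20390 and AT1G24370 on chromosome 1.

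The overlap of the responses asks whether active BZR1 and the PIFs act on the same genes. XTH18, IAA19, SAUR9 and PRE6 were higher in bzr1-1D and lower in pifq, both against Col-0, and CHS and HEMA1 were lower in bzr1-1D and higher in pifq. CPD and ROT3, in contrast to these, were lower in both. Of 8134 genes called in both comparisons, 4765 (58.6%) went in opposite directions. Higher in bzr1-1D and lower in pifq were 2699 genes (1993 for independent lists of these sizes), and lower in bzr1-1D and higher in pifq 2066 (1771). Higher in both were 1461 (2088) and lower in both 1908 (1690).

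Both comparisons share the Col-0 libraries, which alone give a positive relation. In simulations of unchanged genotypes against these libraries, fold changes correlated at r = 0.468, with 65.9% of genes of the same sign and a mean of 0.25 genes called in both. The observed r was 0.016 (Spearman rho −0.096, across genes), with 46.0% of the same sign. The covariance was 0.0132 against 0.0258 simulated, a difference of −0.0126. Every genotype was simulated at the Col-0 means, and the simulated counts were not filtered. The simulated covariance therefore need not equal the part that the shared libraries add here. A test added after seeing the data used 1 Col-0 library for each comparison, with the spread taken from the other 3 genotypes. There 4016 of 6672 genes called in both (60.2%) went in opposite directions, and 4000 of 6599 (60.6%) did with the libraries swapped. Covariances were 0.0076 and 0.00219, with r = 0.00865 and 0.00248 and Spearman rho of −0.118 and −0.117. These covariances were positive where the difference from the simulation was negative. The sign of the covariance without shared libraries is therefore not settled. With the average effects of bzr1-1D and pifq over both backgrounds, 8019 of 10190 genes called for both (78.7%) went in opposite directions, with r = −0.280. A gene that differs in bzr1-1D alone or in pifq alone enters both averages with opposite signs, as XTH18 and CHS do.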

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

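The interaction test was fixed before the data were examined, whereas the tests of explanations given here, on gene order and chromosomes, were chosen after the results were seen.

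The difference between bzr1-1D and its control changed with the PIF background, by the interaction test, for 10363 genes, and 2161 genes were called in opposite directions in the 2 backgrounds. A sequence difference of the bzr1-1D line that pifq;bzr1-1D does not carry would also be called as an interaction. The fixed lists that passed the interaction test had median log2 values of 0.47 for the mutated genes, −0.23 for photosystems, −0.45 for carbon fixation, −3.14 for flavonoid biosynthesis, 0.33 for the clock and 4.68 for seed storage, or 4.06 for seed storage with SESA2 set against the floor of 3 counts per library. None of the 6 passed with an estimated correlation (adjusted p = 0.133 to 0.612), and on chromosomes 2, 3 and 4 alone the mutated genes (adjusted p = 0.125), carbon fixation (0.0578) and flavonoid biosynthesis (0.342) did not pass. The highest single values were SESA5 at 8.83, CRU3 at 8.70, AT5G28145 at 8.48, AT1G20400 at 8.26, AT1G68250 at 8.08 and AT1G20390 at 8.0. The lowest were AT1G24370 at −8.79, AT1G10110 at −6.83, AT5G55360 at −6.57, AGP22 at −5.31, AT1G27570 at −5.29 and AT5G59650 at −5.26. For AT1G20400, AT1G68250, AT1G24370 and AT5G55360 these are fitted values with about 3 counts or fewer per library in a genotype, and they are no bounds. Without pifq replicate 1 the interactions of AT1G24370 and AT5G55360 were no longer called, at log2 values of −4.38 and −3.39. After thinning, that of AT5G55360 was −5.93 and also not called (edgeR adjusted p = 0.0707). Outside the gene counts, reads assigned to no gene averaged 3.75% in pifq and 4.00% in pifq;bzr1-1D, against 3.41% in Col-0 and 2.73% in bzr1-1D.

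A first pattern is the group of 41 genes nearly absent in bzr1-1D alone. On chromosomes 1 and 5 lay 92.7% of them (exact binomial 95% interval 80.1% to 98.5%, against 49.5% of all nuclear genes tested, two-sided p = 4.2e-09). For these 41 genes as a set, the lower bound of 80.1% argues against an allele effect, seen only with the PIFs, that strikes genes wherever they lie. Genes lowered as far in pifq;bzr1-1D, which carries the same allele, were left out by the choice of the set. The bound therefore does not bear on allele effects shared by both backgrounds. CRA1, counted here on chromosome 5, was among the 9 of 12 seed storage genes that fell in bzr1-1D. For CRA1, a change of that list was not told apart from an effect of its place. The bzr1-1D line may hold sequence of another background on parts of chromosomes 1 and 5, whose transcripts map poorly or are missing. That may account for the 38 genes there, as a hypothesis found and tested on the same data. It would not cover the other 3, which lie on chromosomes 2, 3 and 4. In pifq;bzr1-1D against pifq the median log2 fold change of the chromosome 5 members was −0.61 and that of the chromosome 1 members 0.12. The difference was −0.72 (two-sided permutation p = 0.00052, 38 genes), so pooled pifq;bzr1-1D seedlings could still carry part of the chromosome 5 sequence. The permutation and the binomial test both count genes as independent. Linked genes and near-identical copies, such as AT5G50565 and AT5G50665, would move together, so both p-values may be too small.

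Among genes 2- to 16-fold lower in bzr1-1D, 425 of 773 (55.0%, exact binomial 95% interval 51.4% to 58.5%) lay on chromosomes 1 and 5, a small excess over 49.5%. The share was 53.7% for genes higher by as much in bzr1-1D. For interactions of that size it was 55.6% (52.0% to 59.2%) of 750 positive and 50.8% (48.1% to 53.6%) of 1316 negative ones. In pifq against Col-0, which holds no bzr1-1D library, it was 50.3% for genes lower and 45.4% (42.7% to 48.2%) for genes higher by as much, a departure of similar size. For these 773 genes, sequence of another background and an effect of BZR1 therefore cannot be told apart by their chromosomes, and either may account for some of them.

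Another pattern is a run of genes nearly absent in both genotypes without the PIFs. Of 13924 genes with 5 CPM or more in Col-0 and bzr1-1D, 10 were over 16-fold lower in both pifq genotypes, namely CER1, HFR1, AT1G16850, AT2G42100, AT2G42170, AT2G42750, AT2G42770, AT2G42780, CSY3 and PIL1. The longest run of neighbours among them was 4 genes, 20 to 24 tested genes before PIF4, while the longest run over 10000 random placements was 2 (permutation p = 1e-04, the smallest they can give, 10 genes placed). That argues against loss of PIF activity acting on each gene wherever it lies as the source of the run, though it leaves it open for the genes outside the run, HFR1 and PIL1 among them. A lesion or linked sequence variant of the pifq line on chromosome 2 is a candidate explanation. AT2G42100 and AT2G42170, outside the run, also lie near PIF4, at 79 and 72 tested genes before it. AT2G42760 lies among the 4 genes of the run but was under the limit of 5 CPM. It had 2.91 CPM in Col-0, 3.48 in bzr1-1D, 0.0195 in pifq and 0.018 in pifq;bzr1-1D.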

How the results depend on the processing

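The restriction to chromosomes 2, 3 and 4, the choice of genes by average effect and the split of the Col-0 libraries were made after seeing the data, and the other alternatives before. Counts of called genes stayed within 1.5 times of those reported under every alternative except chromosomes 2, 3 and 4 alone, where 10641 genes were tested and, with fewer genes by construction, 5808, 6677, 5942, 6841 and 5056 were called in the order of the report (54.6% of the genes tested in bzr1-1D against Col-0, in place of 56.8%). Genes of 2-fold or more fell from 2415, 2686, 1617, 3556 and 2271 to 807, 1239, 491, 1392 and 811 with the stricter filter, which tested 13150 genes, and to 1054, 1392, 797, 1690 and 1019 on chromosomes 2, 3 and 4. The excess of higher over lower genes depended on the setting, with 5306 higher and 5322 lower in bzr1-1D after thinning, 6029 and 5916 with only the 2 genotypes compared and 6040 and 5966 without pifq replicate 1, and with 6495 higher and 6869 lower in pifq with RLE size factors. In pifq;bzr1-1D against pifq it turned to 4987 higher and 5628 lower after thinning, and lower genes also outnumbered higher ones with RLE size factors, no filter or the stricter filter, on chromosomes 2, 3 and 4, and without any 1 library of these genotypes (4573 and 5136 without pifq;bzr1-1D replicate 1). In pifq;bzr1-1D against bzr1-1D it turned with RLE size factors, DESeq2 and only the 2 genotypes compared (6755 and 6870). Negative interactions outnumbered positive ones under every alternative. DESeq2 called 9024, 10505, 8855, 11210 and 7229. With 1 library left out the counts were 10275 to 12334, 11556 to 13450, 9709 to 11906, 11941 to 14009 and 9005 to 9949, the lone library of a genotype being assumed to vary like the others. The share of genes called in bzr1-1D that were called the same way without the PIFs, 45.2% over both directions, was 44.2% without a filter, 50.2% with the stricter filter, 41.5% with DESeq2, 43.7% after thinning, 46.4% with only the 2 genotypes compared, 46.7% on chromosomes 2, 3 and 4, and 38.1% to 47.0% with 1 library left out. It was 92.7% for genes taken by average effect, a selection that largely fixes a high share, so this is no estimate for the genes called. The share in opposite directions in bzr1-1D and pifq, 58.6%, was 61.0% with the stricter filter, 60.1% with DESeq2, 60.2% on chromosomes 2, 3 and 4, 78.7% with average effects, 60.2% and 60.6% with the Col-0 libraries split both ways, and 57.1% to 59.2% with 1 library left out. Beyond the number of genes tested and the way genes were taken, the cause was not tested. Of the 105 list tests 44 passed, against 0 with an estimated correlation, 91 with fry, 21 on chromosomes 2, 3 and 4 (19 of them among the 44), 43 with RLE size factors and 41 to 44 with 1 library left out. The replicate numbers did not pair the libraries (correlations of deviations −0.0199 to 0.0299), and with the replicate number as a block 12078, 13276, 11842, 13881 and 10393 genes and 42 lists were called (all but cellulose synthases in pifq and the mutated genes in pifq;bzr1-1D against pifq, both at an adjusted p of 0.0549), and the shares were 45.3% and 58.7%. For the 465 gene results under the named-gene rule, 7905 of 7965 alternative values kept direction and side of the threshold, 60 lost the call (38 of them with 1 library left out) and 0 reversed. The smallest library, 16.1 M counts, limits what can be said of genes under 0.186 CPM there.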

Other observations

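The lists tell little of genes outside them, and a few genes with values in 1 genotype were picked after their values were seen. Far higher in pifq;bzr1-1D than in each other genotype, by over 16-fold, were AT1G26240, AT4G12735 and CYP82C2. In pifq alone AT1G52770, AT1G52920, AT1G52990 and CHS were that far higher, and AT1G52618 was nearly absent at 0.0584 CPM against 2.51 to 2.79 CPM elsewhere. Of these, all but CHS have codes close to each other on chromosome 1. By the choice of these genes, pifq;bzr1-1D, which lacks the same PIFs, did not share their levels. For them, an effect of losing the PIFs seen only without bzr1-1D was not told apart from a linked sequence variant. In Col-0 alone AT4G08990 (33.8 CPM), DMT2 (172 CPM) and AT5G28145 (327 CPM) were that far higher, so that the other 3 genotypes shared low levels of them. PRP2, a gene for a proline-rich wall protein, had 331 CPM in bzr1-1D against 13.5, 8.31 and 11.8 in Col-0, pifq and pifq;bzr1-1D, and lies on chromosome 2.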
